A study of Rattus norvegicus with 6 samples.

How the data were processed

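Pancreatic islets are the endocrine cell clusters of the pancreas. RNA of islets from adult male rats and from pools of rats aged 10 days (P10) had been labelled with Cy3 and hybridised, 1 sample per array, to an Agilent array with probes for mRNAs and long non-coding RNAs (lncRNAs). There were 3 arrays per stage, which the labels describe as 3 adult rats and 3 pools. The adult age and the sex of the P10 rats are not given in the labels used here.

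The deposited scanner files hold spot intensity values in 1 channel, read with Agilent Feature Extraction 11.0.1.1 per the submitters' processing notes. Per the file headers, the processed intensity had been background-subtracted and detrended but not scaled between arrays. The authors also deposited 2 tables of normalized log2 values, for 11062 mRNA and 4976 lncRNA probes, with no method stated in the sources used here. Compared with the scanner values, these log2 values lay within 0.05 of quantile-normalized processed signals for 99.99% of the mRNA and 96.05% of the lncRNA entries. Their column medians ran from 9.92 to 9.94 for mRNA and from 7.39 to 7.58 for lncRNA. No column was left unmatched to a sample.

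Each array held 42136 spots that were not controls, from 24684 probes. Probes were classed by the authors' table that listed them, or otherwise by their identifiers, giving 15323 protein-coding, 9319 lncRNA and 42 unclassified probes. Symbols came from RefSeq accessions matched to a gene table of the GRCr8 assembly, which named 14274 protein-coding and 20 lncRNA probes. The array annotation uses an older build, so no coordinates are given. Spots flagged as outliers were left out, and the log2 values of the remaining spots of a probe were averaged. From each array its 75th percentile of log2 signal was subtracted. Probes were tested if well above background on all 3 arrays of at least 1 stage and measured in every replicate counted, which left 12540 protein-coding and 5802 lncRNA probes.

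Before averaging, the arrays of each stage were compared in pairs. For 231 to 239 genes with 2 bright probes, the difference between 2 arrays at one probe was correlated with that at the other probe, with a permutation test of 100000 resamples, two-sided. Spot noise is independent between probes, so a real difference between samples recurs at both. Adult arrays 2 and 3 gave a rho of 0.09 (permutation p = 0.176), and P10 arrays 1 and 2 a rho of 0.09 (permutation p = 0.147). The other pairs gave 0.62 and 0.62 in adults, and 0.30 and 0.28 at P10, with permutation p-values of 1e-05 to 2e-05, the first being the smallest these resamples can give. Between 2 spots of one probe, array differences correlated with r of 0.10 for adult arrays 2 and 3 and 0.12 for P10 arrays 1 and 2. The other P10 pairs gave r of 0.29 and 0.17, and the other adult pairs 0.88 and 0.86. A small difference within the first 2 pairs thus stays possible. Over probes printed 3 times, the variance between adult arrays 2 and 3 was 0.94 of that predicted from the spread of spots within arrays (95% bootstrap interval 0.854 to 1.04), and between P10 arrays 1 and 2 it was 0.95 (0.872 to 1.03). The other P10 pairs gave 1.10 and 1.08, so the P10 case is close, and the other adult pairs gave 13.8 and 11.8. The spread between adult replicates is thus the gap of array 1 to arrays 2 and 3, which were on another slide, and cannot be told apart from a difference between slides. The 2 pairs that did not differ were each averaged and counted as 1 sample, giving 2 replicates per stage. This was decided after the values were seen but before the calls with averaged arrays were computed, and the calls with all 6 arrays had been seen. The design fixed before the data were examined took all 6 arrays as separate samples, and that fit is given as an alternative.

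The contrast of adult minus P10 was fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment over all probes tested and a threshold of 0.05. Gene lists, 31 in all, had been fixed before the data were examined and were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. With 2 replicates per stage the estimated correlation and its test rest on few samples. A list that does not pass there is thus neither backed nor refuted. Each gene entered with its brightest probe. Of 258 genes with more than 1 tested probe, 4 had probes called in opposite directions. Some probes were not well above background on any array of one stage. Their signals there were raised to the lowest well-measured signal of the array where they lay under it. A fold given as at least a value, called a lower bound, is taken from these signals. The detection limit of a single probe can lie higher, so such folds are approximate and not strict lower bounds. Nearest tested protein-coding neighbours of named lncRNAs were compared by Pearson's r with an exact permutation test over all 362880 orders. Shares of marker genes were given exact binomial intervals. Data were simulated with 18362 probes, of which 200 were changed. In these limma called 0% of 2-fold, 29.9% of 4-fold and 50% of 8-fold changes, and 0 unchanged probes. In the real data 52.34% of tested protein-coding probes were called, and the adjusted threshold depends on the share of changed probes. The simulated percentages thus do not give the power of the real comparison.

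Genes named in the text follow a rule fixed beforehand. It took the 10 largest rises and falls among called protein-coding genes measured on all 6 arrays with no overlap between stages, 5 lncRNAs each way, 3 lower bounds each way, up to 4 members of each list with the largest change, and a set of islet genes always named if tested. Genes of 10 further marker lists were chosen after the values were seen, and are said to be so where they appear. Alternatives changed the background correction (normexp, offset 50, on spot medians because mean signals are not among the columns), the scaling, the source of the values, the filter, the variance model, the slide, the replicate number as a block, and the arrays used. Some genes that the rule takes are not reported here, and Pdx1, Mafa, Mki67, Meg3, Malat1, Xist and the list of sex-linked genes were not analysed here. Figures were drawn with matplotlib 3.10.9.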

Results

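Transcripts of rat pancreatic islets were measured in adults and at postnatal day 10 (P10) to describe how lncRNAs and mRNAs differ between immature and mature islets. Each stage had 3 arrays. Between 17829 and 18731 of 24684 probes were well above background per array, and 0 were saturated. Adult arrays 2 and 3 showed no difference that passed the test against measurement noise and were counted as 1 sample. So were P10 arrays 1 and 2, which leaves n = 2 per stage throughout. The labels name separate rats and pools, and the values do not settle whether these arrays carry separate RNA. Levels are log2 signal relative to the array's 75th percentile, changes are adult minus P10 in log2 with their standard error (SE), and p-values are limma's. The number of arrays limits the precision.

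Genes of mature beta cells, the insulin-secreting cells, were higher in adult islets. Of 18 measured, 15 were higher, 0 lower and 3 did not pass the test, and the median was 6.27-fold higher. The glucose transporter gene Slc2a2 stood at 4.42 ± 0.26 (SD, n = 2) in adults and 1.24 ± 0.02 (SD, n = 2) at P10, a rise of 3.18 (SE 0.18, limma adjusted p = 0.00175). Ucn3, which encodes the peptide urocortin 3, rose by 2.67 (SE 0.22, limma adjusted p = 0.00291). The prohormone convertase gene Pcsk1 rose by 3.57, the prolactin receptor gene Prlr by 3.34 and Wnt4 by 3.19. Genes of secretory granules and exocytosis were higher too, 23 of 26, with 2 lower. Among these Syt4, a synaptotagmin, rose by 4.59 and Ptprn, of the granule membrane, by 4.57. Camera gave an adjusted p of 1.61e-07 for the mature beta cell list and 5.45e-08 for the granule list, and with an estimated correlation the adjusted p was 0.495 for each. The estimated form rests on 2 replicates per stage and does not decide, here and below. Other cell markers differed on the same arrays. Endocrine transcription factors, a list chosen after the values were seen, moved with both lists, with a median of 2.51. In the opposite direction, 24 of 28 acinar (11 with quantile normalization) and 27 of 31 enterocyte markers were higher at P10.

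Islet transcription factors went both ways, 8 of 18 being higher and 7 lower. Nkx6-1, of beta cells, rose by 2.92. Lower were Gata4 at -5.58 and Nr5a2 at -4.24. Acinar and enterocyte markers were higher at P10 on the same arrays, and the cells behind these falls were not resolved. Alpha cell genes were higher in 8 of 11 cases and lower in 2 (camera adjusted p = 0.0203, adjusted p = 0.495 with an estimated correlation). Of 9 genes listed for immature beta cells 6 were lower and 0 higher (camera adjusted p = 0.0354, adjusted p = 0.644 with an estimated correlation), among them Dlk1, an imprinted Notch-family ligand, at -6.40.

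The direction of the main hormone genes, or whether they passed the test, depended on the scaling. The 75th percentile of log2 signal, which the main scaling subtracts, was 10.93 to 11.36 on adult arrays and 9.92 to 9.99 at P10. It is subtracted from all probes of an array alike. The 99th percentile differed less between stages, at 15.93 to 16.31 on adult arrays and 15.6 to 15.61 at P10. After the subtraction the brightest probes thus stand lower in adults relative to P10. Ins1, Ins2 and Gcg ranked above the 99th percentile of tested probes in both stages. Ins1 was lower in adults by the main scaling, at -0.93 (SE 0.20, limma adjusted p = 0.0248), and so was Gcg, at -0.80 (SE 0.22, limma adjusted p = 0.0436). With quantile normalization the values were 0.18 (limma adjusted p = 0.291) and 0.32 (limma adjusted p = 0.083). Ins2 stood at -0.58 (limma adjusted p = 0.23), Iapp at 0.47 (limma adjusted p = 0.109) and Sst at 0.03 (limma adjusted p = 0.883). With quantile normalization Iapp and Sst were higher and passed the test, at 1.5 and 1.09, and Ins2 stood at 0.45. The pancreatic polypeptide gene Ppy rose by 1.72 (SE 0.15, limma adjusted p = 0.0032), or 2.47 with quantile normalization, while the ghrelin gene Ghrl stood lower, at -1.43, and the cholecystokinin gene Cck at -5.14. Cck is also a gut hormone gene, and the gut hormone gene Sct stood at -5.06 and the enterocyte markers described further on at a median of -4.58. Of 12 islet hormone genes 2 were higher and 4 lower, or 5 and 2 with quantile normalization.

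**Figure D1:**
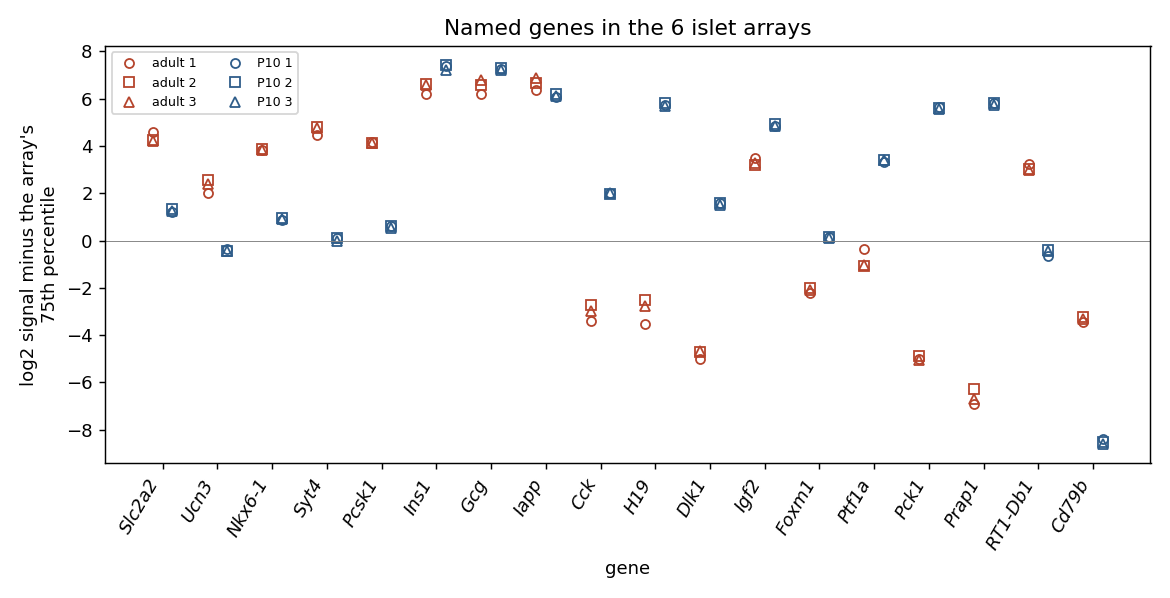
Log2 signal minus the array's 75th percentile (vertical axis) for selected genes in each of the 6 arrays, adult in red and P10 in blue, with 1 symbol per array of a stage. For Slc2a2 the adult points lie above the P10 points, and for H19 and Prap1 far below them.

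Cell cycle genes were lower in adults. Of 26 S phase genes 21 were lower and 2 higher, and of 21 G2/M genes 18 were lower and 0 higher, with median falls of 3.72-fold and 3.37-fold. The chromatin assembly gene Chaf1b stood at -3.30 (SE 0.16, limma adjusted p = 0.00149), the mitotic transcription factor gene Foxm1 at -2.27 and Aurkb at -2.09. Camera gave adjusted p-values of 7.47e-06 and 7.18e-06, and with an estimated correlation the adjusted p was 0.495 for both. The imprinted growth genes H19, Cdkn1c and Igf2 stood at -8.82, -4.96 and -1.49, although the 13 imprinted genes as a list gave 4 higher and 6 lower. All P10 arrays in which cell cycle and immature beta cell genes were higher also carried transcripts of enterocyte genes, given further on.

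Markers of other cells differed as well. Of 24 leukocyte markers 22 were higher in adults and 0 lower, with a median of 3.46-fold (camera adjusted p = 3.35e-09, adjusted p = 0.495 with an estimated correlation). The class II gene RT1-Db1 rose by 3.61. The B cell gene Cd79b, not well above background at P10, was at least 13.5-fold higher (limma adjusted p = 0.00131), and the myeloid integrin gene Itgam at least 14.2-fold. Of 28 markers of acinar cells, which secrete digestive enzymes, 24 were lower in adults and 2 higher (camera adjusted p = 2.18e-05, adjusted p = 0.644 with an estimated correlation). With quantile normalization 11 were lower and 3 higher. The acinar transcription factors Rbpjl and Ptf1a stood at -6.12 and -4.08.

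Some of the steepest falls were in genes best known from intestinal epithelium, and 14 of the 50 largest falls of protein-coding genes were on intestinal marker lists chosen after the values were seen. Prap1 stood at -6.72 ± 0.30 (SD, n = 2) in adults and 5.77 ± 0.06 (SD, n = 2) at P10, a difference of -12.49 (SE 0.20, limma adjusted p = 0.0011). Mttp, which loads lipid onto lipoproteins, stood at -10.12, the intestinal alkaline phosphatase gene Alpi at -9.96, Cdhr5 of the brush border at -9.07 and the chloride exchanger gene Slc26a3 at -7.74. The gluconeogenic gene Pck1 stood at -10.59. With quantile normalization Prap1 and Pck1 stood at -11.65 and -9.99. Apoa4, not well above background in adults, was at least 7730-fold lower there (limma adjusted p = 0.00112) and Ms4a10 at least 4649-fold lower (limma adjusted p = 0.0011). Of 31 measured enterocyte markers, a list that includes Apoa4, Mttp, Alpi and Cdhr5, which prompted it, 27 were lower in adults and 2 higher. Apoa4, Prap1, Mttp and Alpi were well above background on all 3 P10 arrays, so no P10 array could be left out to remove these transcripts.

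Among protein-coding genes with a gene name that were measured on all 6 arrays, the steepest rise was in Akr1c15, at 5.83 (SE 0.30, limma adjusted p = 0.00152). Next came Reg3g, a secreted lectin, at 5.61, and Aass, of lysine breakdown, at 5.35. Tmem35a followed at 5.28, Gpr15 at 5.24, Jade2 at 5.22 and the protease inhibitor gene Slpi at 5.21. Il1rl1, the receptor gene for interleukin 33, was at least 72.1-fold higher and Wfdc18 at least 62.6-fold higher, with limma adjusted p-values of 0.00155 and 0.00131.

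**Figure D2:**
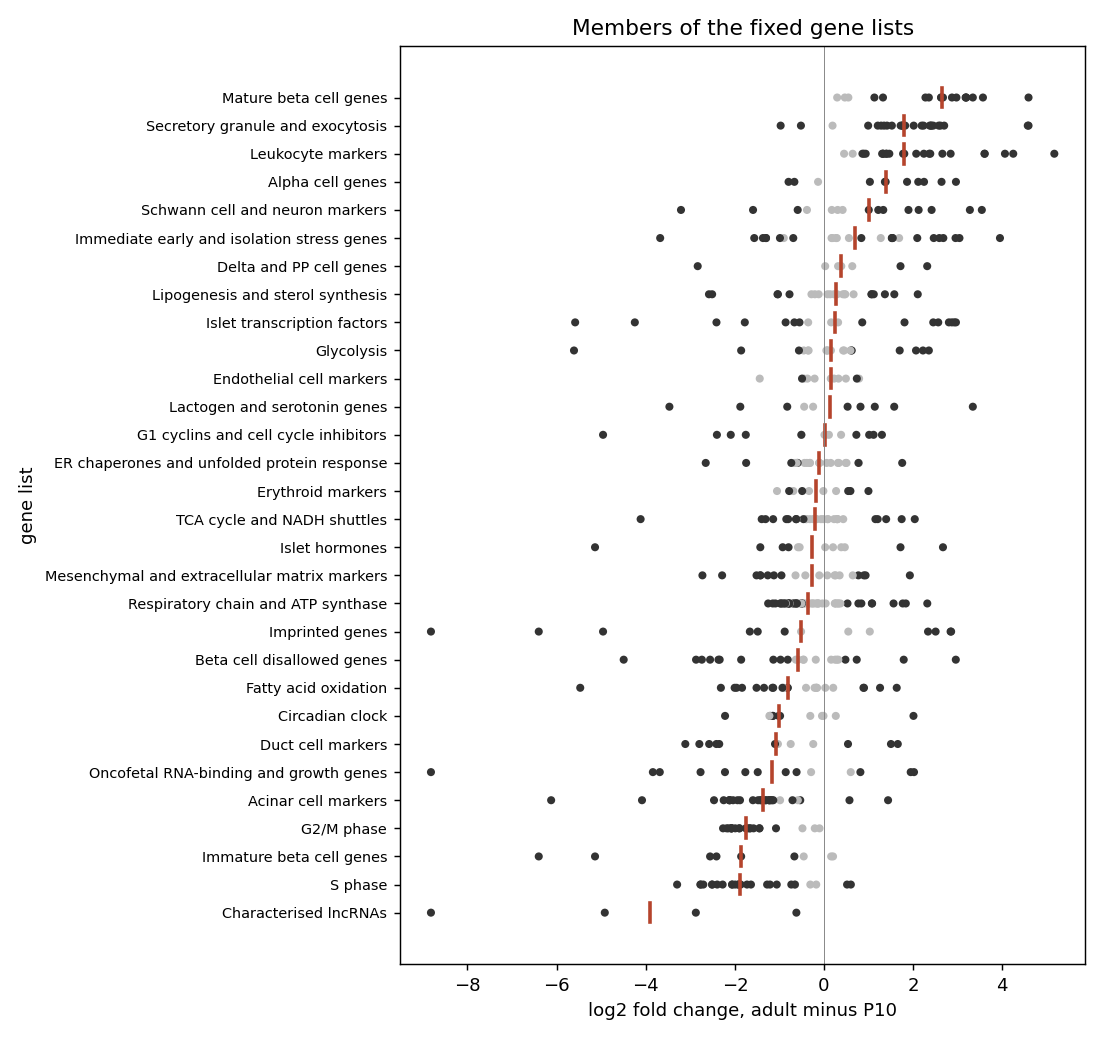
Log2 fold change, adult minus P10 (horizontal axis), of measured members of the fixed gene lists, 1 line per list. Black points passed the test and grey points did not, and red bars mark list medians, which reach from 2.65 for mature beta cell genes to -3.90 for characterised lncRNAs.

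The remaining lists were not called by camera. Respiratory chain genes gave 9 higher and 19 lower of 53, or 12 and 10 with quantile normalization, TCA cycle genes 5 and 9 of 31, glycolysis genes 6 and 3 of 19, and fatty acid oxidation genes 4 and 12 of 24 (camera adjusted p = 0.0814). Lipid synthesis genes gave 6 higher and 5 lower of 22, genes usually silent in beta cells 4 and 10 of 23, G1 cyclins and inhibitors 4 and 5 of 14 (5 and 4 with quantile normalization), and oncofetal growth genes 3 and 9 of 14. Delta and PP cell genes gave 2 higher and 1 lower of 7, duct markers 3 and 6 of 12, endothelial markers 1 and 1 of 11, matrix markers 4 and 8 of 20, Schwann cell and neuron markers 8 and 3 of 15, and erythroid markers 3 and 2 of 10. Unfolded protein response genes gave 2 higher and 4 lower of 22, or 6 and 4 with quantile normalization, clock genes 1 and 6 of 12, and lactogen and serotonin genes 5 and 3 of 10. Immediate early and stress genes were split, 11 of 26 being higher, such as Cxcl2 at 3.95, and 7 lower, such as Egr1 at -3.68. Adjusted over the list alone, 15 mature beta cell genes and 23 leukocyte markers were higher, and 26 acinar markers lower.

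Across all probes, limma called 2957 protein-coding probes higher and 3607 lower in adults, of which 1988 and 2598 changed at least 2-fold. Among lncRNA probes 945 were higher and 2087 lower, 686 and 1756 of them at least 2-fold. With every array as its own replicate the counts were 4075, 4830, 1346 and 2741, without P10 replicate 3 they were 1186, 1549, 388 and 1041, and with normexp 1707, 1959, 417 and 760. Lower calls made up 68.8% of called lncRNA probes, against 56.1% with quantile normalization, which called 1462 higher and 1867 lower. For protein-coding probes the balance turned, with 3748 higher and 3408 lower under quantile normalization. Median scaling gave 3800 and 2791 protein-coding probes, and the authors' normalized values 3237 and 2965. Over all tested probes the median change was -0.23, and -0.02 with quantile normalization.

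Few lncRNA probes carry a gene name. H19, transcribed from an imprinted locus, stood at -8.82 (SE 0.35, limma adjusted p = 0.00131), the RNase P RNA gene Rpph1 at -4.92, the telomerase RNA gene Terc at -2.88 and Gas5 at -0.62. Rpph1 was well above background on only 1 of the 3 adult arrays, and with quantile normalization Rpph1 and Terc stood at -4.24 and -2.26. These 4 of 4 characterised lncRNAs were lower (camera adjusted p = 0.03, adjusted p = 0.644 with an estimated correlation). Across 9 named lncRNAs and their nearest measured protein-coding neighbours, changes gave a Pearson r of 0.15 (exact permutation p = 0.703) and a Spearman rho of 0.18 (exact permutation p = 0.644), both two-sided and across genes, which are not independent replicates. H19 lies near Mrpl23, which stood at -1.45, and Rpph1 near Parp2, at -0.11 (limma adjusted p = 0.505).

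**Figure D3:**
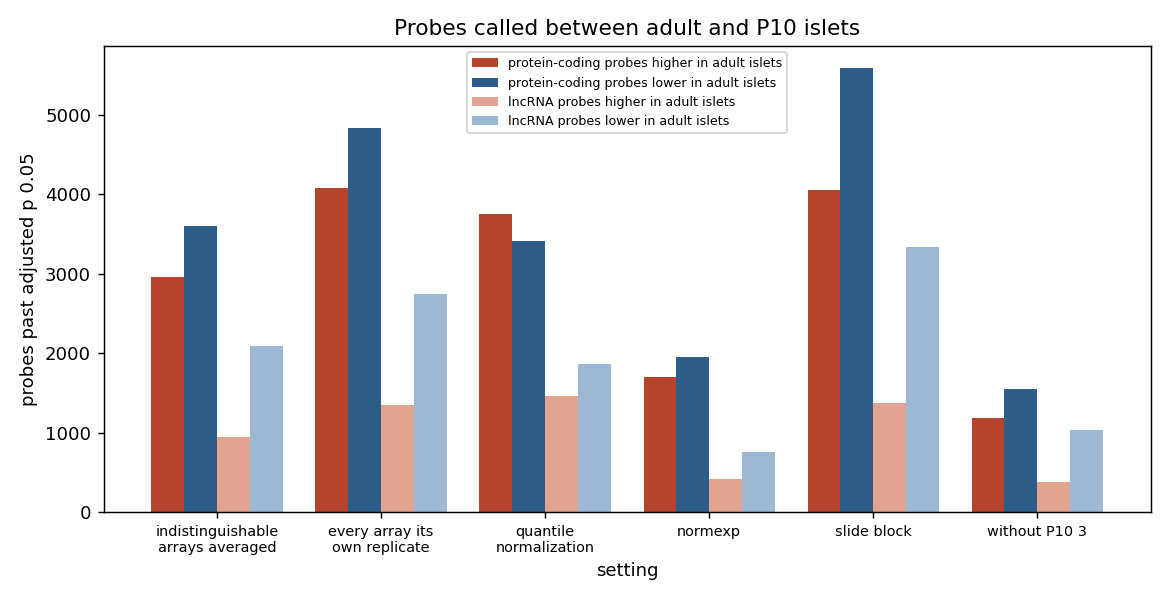
Number of probes past an adjusted p of 0.05 (vertical axis) in each class and direction under 6 settings. With indistinguishable arrays averaged, on the left, there were 2957, 3607, 945 and 2087, fewer than with every array as its own replicate and more than with normexp.

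Slide and stage overlapped in part, since slide 1 held adult array 1 and the P10 arrays, and slide 2 held adult arrays 2 and 3. With the slide as a block 5587 protein-coding and 3339 lncRNA probes were lower in adults, and on slide 1 alone 5566 and 3334. Both rest on the 1 adult array of slide 1, assumed to vary like the P10 arrays. List medians on slide 1 alone were 2.44 for mature beta cell genes, 1.73 for granule genes, 1.72 for leukocyte markers, 1.33 for alpha cell genes, -1.90 for S phase genes, -1.75 for G2/M genes, -1.65 for acinar markers and -1.91 for immature beta cell genes. Slide 2 held no P10 array and gives no value of its own.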

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

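The tests of intestinal genes, scaling, endocrine share and slides were chosen after their results were seen, while those of hepatocyte markers and of other splits of the counted replicates were not, although the splits of all 6 arrays had been seen before the latter. Outside the 2 probe classes compared, 11 of the 20 tested unclassified probes passed the threshold. That is 55%, near the 52.34% of protein-coding and 52.26% of lncRNA probes. Groups of 3 arrays were too small to test for outlying arrays.

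Enterocyte genes were higher at P10, also with quantile normalization (median -4.496), which argues against scaling as the cause, while liver in the P10 pools stays open, since 46.15% of 13 hepatocyte markers were lower in adults (95% exact binomial interval 19.2 to 74.9). Intestinal epithelium in the pools may be a source: 90.91% of 11 brush border, intestinal transcription factor and goblet cell genes not named before were lower in adults, Cdh17 at -6.96 and Cdx2 at -4.01 among them but not Ccl6 at 3.37. Of these 11, Cdh17, Cdx2, Krt20 and Vil1 are also on the enterocyte list, so the share in part recounts the pattern itself. Among P10 signals Fabp1 and Fabp2 stood at the 99.4 and 99.1 percentiles, Vil1 at 97.6 (93.0 in adults) and Cdx2 at 64.3, ranks that also depend on each probe's affinity. A first version of this test, on 6 genes including ones already seen, was replaced, and the explanation was narrowed from intestine to its epithelium because 0 of 5 smooth muscle markers were lower in adults. Of the 31 enterocyte markers 23 were well above background on all 3 adult arrays, and their expression by islet cells of young rats stays open and untested.

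Mature beta cell genes were higher in adults. For a lower share of endocrine cells at P10, leukocyte and acinar markers were compared. The leukocyte median was 1.789 (SE 0.32), or 1.79 (SE 0.37) with quantile normalization, while the acinar median was -1.36 (SE 0.31), or -0.30 (SE 0.34). Here and below, the SE of a median is taken across the genes of a list, not across replicates. These medians cannot decide, since cells that dilute endocrine cells at P10 would dilute leukocytes as well. This test replaced one whose value went with a lower endocrine share. In it, 6 endocrine transcription factors, which share members with the fixed lists, had a median of 2.51. The beta cell median exceeded theirs by only 0.14 (SE 0.77). A lower share, as the whole cause or in part, stays open. A difference between slides as the whole cause is argued against by the median of 2.438 (SE 0.36) on slide 1 alone, where slide cannot differ but only 1 adult array is held. Maturation with age stays open, as the design names it.

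More lncRNA probes were lower than higher in adults. Scaling may account for part of this, since the share of lower calls came to 56.08% with quantile normalization. A difference between slides as the whole cause is argued against by the share of 70.46% on slide 1 alone, although these calls rest on 1 adult array and take their spread from the P10 arrays. A change of lncRNA levels with age stays open and was not tested.

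The 4 counted replicates allow 3 splits, too few for a share under 0.05, and for each result only the real split, 1 of 3, gave as many calls. It called 6564 protein-coding probes, 3032 lncRNA probes and 9 lists, and the highest other split 0 of each. With every array as its own replicate there are 10 splits, also too few, and the real one called 8905 protein-coding probes, 4087 lncRNA probes and 9 lists, the highest other 0, 0 and 9. The other split with 9 lists set adult array 1 with P10 arrays 1 and 2 against the rest, and the remaining mixed splits called 6 to 8. Each mixed split of the 6 arrays still has more arrays of 1 stage on one side, so part of the stage difference remains in it. Its list calls thus do not show whether camera's preset correlation calls lists without a stage difference. In mixed splits the stage difference also widens the spread within groups, so the 0 called probes do not decide either.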

How the results depend on the processing

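Averaging only the adult pair, slide 1 alone and quantile normalization with the slide block were chosen after seeing the data. So was the replicate block with every array as its own replicate. Every array as its own replicate, without a block, was the design fixed beforehand, and became an alternative after the data were seen. For named genes, 2775 comparisons with an alternative kept direction and side of the threshold, 44 lost and 54 gained the call, and 9 turned. For gene lists 585 were the same, 20 lost and 25 gained the call. The cause was not tested unless given. Normexp called 1707 protein-coding probes higher and 1959 lower, and 417 lncRNA probes higher and 760 lower. Quantile normalization called 1462 lncRNA probes higher, and with the slide block 4700 protein-coding and 1885 lncRNA probes higher. Without a filter on dim probes, which tests more probes, 4011 lncRNA probes were lower. The slide block gave 5587 protein-coding and 3339 lncRNA probes lower, and slide 1 alone 5566 and 3334. Leaving out 1 array in turn gave 1186 to 4260 protein-coding probes higher and 1549 to 4756 lower, and 388 to 1604 lncRNA probes higher and 1041 to 2782 lower, the lowest without P10 replicate 3 and the highest without adult replicate 1. These 2, slide 1 alone and the slide block leave 1 stage with a lone counted sample, assumed to vary like the other stage. Camera called 9 lists, 0 with an estimated correlation, and fry, which does not compare a list with other genes, 23. With an estimated correlation, camera's smallest unadjusted p over the lists was 0.0342, for leukocyte markers. That form rests on 2 replicates per stage, so its 0 calls do not decide against the lists. Without 1 array 8 to 10 lists were called, and r of the neighbour pairs was 0.1253 to 0.1655.

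Ins1 turned to 0.1754 with quantile normalization, 0.1758 in the authors' tables and 0.1956 with quantile normalization and the slide block, and Gcg to 0.3217, 0.3238 and 0.2938. Erg turned to 0.1061 with the last of these, and Ghsr to -0.4506 with the slide block and on slide 1 alone. The replicate block gave 3589 and 4291 protein-coding and 1214 and 2559 lncRNA probes higher and lower, against 4075, 4830, 1346 and 2741 for the same arrays without it. Same-numbered arrays deviated together with r of -0.21, 0.08 and -0.24, so the numbers do not pair the samples. With only the adult pair averaged the counts were 3718, 4635, 1208 and 2684. Signal over background limits dim probes, whose dimmest group had a median of -1.14, against -0.17 with quantile normalization.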

Other observations

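Immune cell markers were counted in lists chosen after the values were seen, which were not tested against each other. Of 9 macrophage markers 9 were higher in adults, with Adgre1 at 2.26 and the complement gene C1qa at 1.78. Of 10 T cell markers 6 were higher and 0 lower, Cd3e at 1.47 among them. B cell markers were split, 4 of 8 being higher and 2 lower. Cr2, not well above background at P10, was at least 5.22-fold higher, while Pax5 stood at -2.02. With an estimated correlation, camera's adjusted p was 0.224 for the macrophage, 0.512 for the T cell and 0.535 for the B cell list.

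Intestinal lists chosen in the same way were mostly lower in adults, 6 of 6 for brush border and intestinal transcription factor genes, 6 of 7 for goblet cell markers with 1 higher, and 3 of 4 for gut hormones with 1 higher. All the brush border and transcription factor genes but Espn are also on the enterocyte list. The secretin gene Sct stood at -5.06 and the tachykinin gene Tac1 at 1.26. Hepatocyte markers gave 6 higher and 6 lower of 13, gut smooth muscle markers 3 and 0 of 5, and endocrine transcription factors 5 and 1 of 6.

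Of 320 tested strand probes of ultraconserved elements 37 were higher and 123 lower in adults, or 77 and 106 with quantile normalization. Lower calls also prevailed among all 5802 tested lncRNA probes, with 945 higher and 2087 lower, or 1462 and 1867 with quantile normalization. Of 71 elements with both strands tested, 14 had both strands called in the same direction and 4 in opposite directions. Whether the strands agreed beyond the excess of lower calls was not tested.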
